A study of Mus musculus with 18 samples.

How the data were processed

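Pancreatic islets of 10 NRK1 beta-cell knockout mice and 8 WT mice were profiled with a 3' end mRNA sequencing kit (QuantSeq FWD) after 12 weeks of high-fat diet, per the labels. The deposited table holds log2 values for 10509 genes in 18 columns, 1 per sample. The submitters' processing notes name STAR 2.5.2, HTSeq 0.6.1, edgeR and the build GRCm38, without saying what each was used for. The annotation, the filter on low genes and the prior count are not given in the sources used here. All columns share a lowest log2 value of -0.83, which is 0.562 CPM on the linear scale. After that floor was subtracted, the linear values of each library were whole multiples of what 1 read is worth, within a tolerance of 0.05 reads for 100% of values in each library. The deposited log2 values are therefore log2 of CPM plus a floor of 0.562, where 1 read was worth 0.238 to 0.411 CPM, and whole read counts were recovered from them. This CPM holds a scaling factor per library. In KO 3 it corresponds to a library size of 2560900, below the 3292303 reads over the listed genes. Fold changes are on this log2 scale, which understates changes of genes with few reads.

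Depth was taken as the sum of recovered reads over the listed genes, 2831137 to 4303680 per library, and the median gene had 60 reads. Reads outside the listed genes were not analysed here. PCR copies are not independent molecules, so read numbers understate the error. Samples were grouped by the genotype label. Labels give no replicate numbers, pairing, sex or batch, so libraries were numbered within a group. Titles carry an animal number, and runs of consecutive numbers were used after the data had been seen. The number of KO 1 has 6 digits and the others have 5, so KO 1 was left in a run of its own. Without its repeated digit it would continue the run of WT 6 and WT 7, and the run values were also computed that way. The 73 pairs of libraries of the same group differed by more than sampling noise, with a chi-square per degree of freedom of 6.01 to 41.3 over genes with at least 10 reads, so each was counted as a separate sample. Gene symbols came with the file, and 10508 of the Entrez identifiers were found in a RefSeq table of GRCm38, from which coordinates were taken.

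The test between genotypes was limma 3.58.1 in R 4.3.3 (linear model per gene, empirical Bayes with a mean-variance trend, no covariate, two-sided) with Benjamini-Hochberg adjusted p under 0.05. A filter of log2 above 0 in at least 8 samples removed 0 genes. The test, the filter, the gene lists, the rule for named genes and a set of alternatives were fixed before the data were examined. The 26 lists with at least 3 measured genes were tested with limma's camera, a preset correlation of 0.01 and adjustment over the lists. Camera was run with the variance trend of the gene test. That option had not been fixed: it was set after an exploratory run with camera's default had been seen. The exploratory run also took in smaller lists and called fewer than 8. Over the same 26 lists the default called the same 8. Not tested were the lymphocyte, erythrocyte and Reg family lists, with 2, 2 and 1 measured genes, the mitochondrially encoded list, with 0, and the sex-linked genes. Camera with an estimated correlation, camera on ranks and the rotation test fry were run as alternatives. Marker scores are the mean log2 value of a list in a library, tested by exact permutation over all 43758 regroupings of the samples, two-sided.

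Named genes followed the fixed rule: Nmrk1, Ins1 and Ins2; the 5 genes of smallest p in each direction, since fewer than 5 passed; and up to 4 members of smallest p in each called list and in 8 lists chosen beforehand. Of these members, 3 are not reported here by name. The fixed alternatives were a stricter filter of log2 above 3 in at least 8 samples, 1 added on the linear scale, median centring, quantile normalization, no trend, robust empirical Bayes, sample weights, an exact rank-sum test, acinar or stromal scores as covariates, a residual principal component, a count test, an adjusted p under 0.10 and leaving out each sample. The count test named beforehand, the submitters' edgeR, was replaced by limma voom on the recovered reads, because the file holds log2 values. Having no filter gave the same genes and so no separate value. Alternatives added after seeing the data left out the 3 libraries with the most genes at 0 reads, left out KO 7 and KO 8, left out those and WT 5, used the 12 libraries of runs of consecutive animal numbers that hold both groups, with and without the run as a term, used 15 libraries with KO 1 in the run of WT 6 and WT 7 in the same 2 ways, and tested list scores by exact permutation. The Ins1 to Ins2 ratio was also added then.

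The limma test, camera and the exact test were tested on simulated data, and the other steps were not. Reads were drawn for the 10509 genes from the means, library sizes and spread of these samples, with 200 genes changed. Limma made 10 false calls among 10309 unchanged genes, which was 7.75% of its calls. Of 200 unchanged lists, 1% had a camera p under 0.05, and the exact test gave a p under 0.05 in 4.7% of unchanged values. The simulation drew genes independently, so it does not test the preset correlation. Bootstrap intervals used 10000 resamples within groups and 95% limits. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.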

Results

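Gene expression was measured in pancreatic islets of mice kept on a high-fat diet for 12 weeks. The comparison asks how islet transcripts differ when NRK1, a kinase that turns nicotinamide riboside into a precursor of NAD, is removed from beta cells with an Ins1Cre driver. The knockout group had 10 mice and the WT group had 8, with 1 library per mouse. Libraries were read at the 3' ends of transcripts, and 10509 genes were listed in every library. Over these genes the libraries held 2831137 to 4303680 reads, with a mean of 3459150 ± 481679 (SD, n = 10) in the knockout and 3429370 ± 389492 (SD, n = 8) in WT. The insulin gene Ins2 alone took 44.6% ± 5.56 (SD, n = 10) of the reads in the knockout and 38.7% ± 3.78 (SD, n = 8) in WT. The number of listed genes with no read ranged from 33 to 346 per library and was largest in WT 7, KO 2 and KO 3, at 346, 320 and 227. Libraries are called KO 1 to KO 10 and WT 1 to WT 8. Reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were present in each of the 18 libraries.

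The targeted gene did not differ detectably, Ins1 was lower in the knockout by an amount that did not pass the test over all genes, and Ins2 was not lower. Nmrk1 (chromosome 19, 18632016 to 18652428, GRCm38) had a log2 CPM of 1.99 ± 0.49 (SD, n = 10) in the knockout and 2.01 ± 0.92 (SD, n = 8) in WT. Its log2 fold change was -0.03 with a 95% interval of -0.75 to 0.70, from 3 to 36 reads per library. The deleted part of the gene is not given in the labels, so 3' end reads of Nmrk1 do not check the genotype labels. Ins1 (chromosome 19, 52264297 to 52265015) had a log2 CPM of 15.36 ± 0.56 (SD, n = 10) in the knockout and 16.04 ± 0.35 (SD, n = 8) in WT. Its log2 fold change was -0.68 with an SE of 0.33 and a 95% interval of -1.36 to 0.00 in limma, with an unadjusted p of 0.0508, an adjusted p of 0.926 over all genes and 0.152 over these 3 genes. Ins2 (chromosome 7, 142678656 to 142679726) had a log2 fold change of 0.28 with a 95% interval of -1.02 to 1.59 and a limma adjusted p of 0.984. Its limma SE was 0.64, although its SD was 0.35 (n = 10) in the knockout and 0.27 (n = 8) in WT. Limma's SE draws on the variance trend over all genes. For Ins1 and Ins2 its intervals and p-values therefore do not measure the spread between mice alone.

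Within a library, Ins1 was lower relative to Ins2 in the knockout. The log2 ratio of Ins1 to Ins2 was -3.40 ± 0.53 (SD, n = 10) in the knockout and -2.44 ± 0.33 (SD, n = 8) in WT, a difference of -0.96 that corresponds to a fold of 0.513. The ratio lay below the WT mean in 10 of 10 knockout libraries and below the lowest WT library in 8. A two-sided exact permutation test gave p = 0.000297 for the ratio, p = 0.00443 for Ins1, p = 0.0757 for Ins2 and p = 0.938 for Nmrk1, with adjusted values over the 4 of 0.00119, 0.00887, 0.101 and 0.938. The ratio and these 4 exact tests were chosen after the values had been seen. In runs of consecutive animal numbers that held both groups, the difference of the ratio was -1.25, -1.21 and -0.76, the last with 1 WT library, and -1.10 over these 12 libraries with the run as a term (exact permutation within runs, p = 0.0208). KO 1 has an animal number with 1 digit more than the others and was left out of these runs, and with it in the run of WT 6 and WT 7 the difference over 15 libraries was -1.01 (p = 0.00694). In that run alone the difference was -0.61, with 1 knockout library. Ins1 and Ins2 are close paralogs, and how reads matching both were counted is not given in the sources used here.

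**Figure D1:**
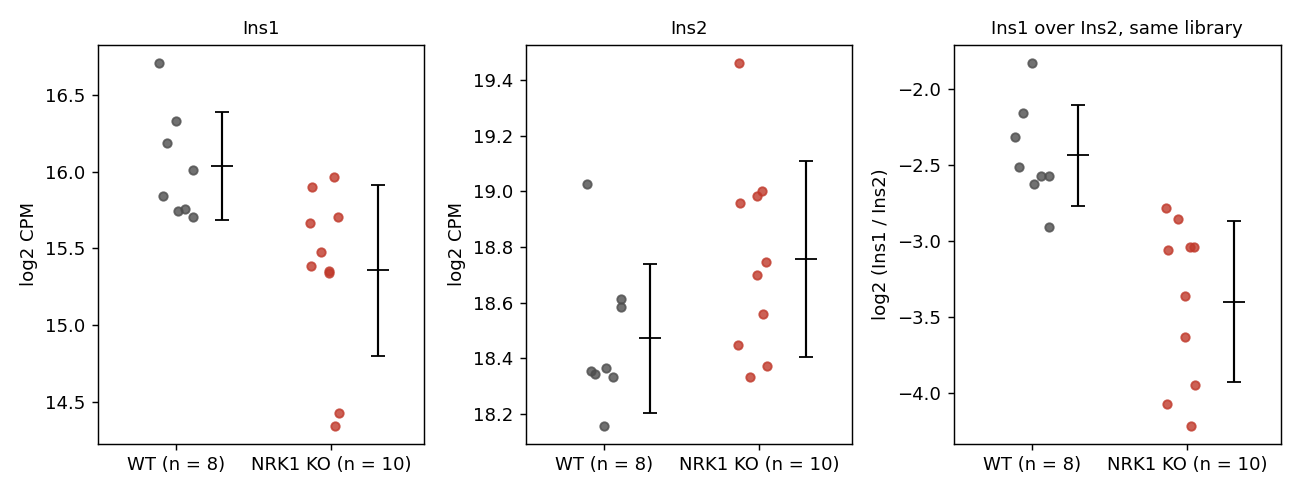
Log2 CPM of Ins1 and of Ins2 and the log2 ratio of Ins1 to Ins2 in the same library, 1 point per mouse, for WT (n = 8) and NRK1 KO (n = 10) islets, with the group mean and SD beside the points. The ratio was -2.44 in WT and -3.40 in the knockout on average, and 8 of the 10 knockout libraries lay below the lowest WT library.

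No single gene passed the test between knockout and WT islets. The genes with the smallest p in the higher direction were Areg, an epidermal growth factor receptor ligand, at a log2 fold change of 1.95 (SE 0.42), Trim30a at 1.73 (SE 0.42), the heparan sulfate synthesis gene Ext1 at 0.91 (SE 0.24), Bin1 at 0.83 (SE 0.21) and Hacd2 at 1.27 (SE 0.34). In the lower direction they were the G protein-coupled receptor kinase Grk5 at -0.81 (SE 0.21), Eci1, an enzyme of fatty acid oxidation, at -0.85 (SE 0.23), Cetn3 at -0.52 (SE 0.14), Sub1 at -0.56 (SE 0.15) and Rnf32 at -1.30 (SE 0.36). All 10 had a limma adjusted p of 0.797 and are given as values that did not pass. Areg, Trim30a, Hacd2 and Rnf32 rested on 0 to 36, 0 to 36, 2 to 28 and 1 to 63 reads per library. Limma called 0 of 10509 genes, with 567 at an unadjusted p under 0.05, of which 334 were higher and 233 lower in the knockout. About 525 would be expected by chance at that threshold. An exact rank-sum test called 0 with 535 at an unadjusted p under 0.05, and limma voom on the recovered reads called 0 with 546. The 95% interval excluded a 2-fold change for 77.1% of genes. In simulated libraries of the same design over 10509 genes, limma recovered 28.4% of genes changed 1.5-fold, 65.7% of those changed 2-fold and 84.8% of those changed 4-fold. The simulation changed 200 genes and drew genes independently. It gave all libraries the same spread per gene, estimated over all of them, whereas the real KO 2, KO 3 and WT 7 had a larger residual spread (SD 0.874, 0.736 and 0.772). These rates may not hold for fewer changed genes or for the real libraries.

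Among 26 gene lists, those of the interferon response, inflammation and the immediate early response were called higher only with camera's preset correlation of 0.01. Camera tests a list against the other genes. Estimated from these data, the correlation was 0.350, 0.306 and 0.119, and with it, fry or exact permutation of list scores 0 lists passed. All 22 measured interferon and antigen presentation genes were higher in the knockout, with a mean log2 fold change of 0.44 (camera adjusted p = 6.89e-07 with the preset correlation, adjusted p = 0.231 with an estimated correlation). Members with a small p were Isg15 at 1.17, Oasl2 at 0.83 and Ifit1 at 1.09, none of which passed over all genes. Of 12 NF-kB inflammation genes, 11 were higher, with a mean of 0.58 (camera adjusted p = 0.00337, adjusted p = 0.300 with an estimated correlation). Nfkb1 was at 0.46, its inhibitor Nfkbia at 0.74, the adhesion gene Icam1 at 1.30 and Socs3 at 0.91, which was 0.48 without WT 7. Of 17 immediate early and heat shock genes, 13 were higher, with a mean of 0.36 (camera adjusted p = 0.00383, adjusted p = 0.231 with an estimated correlation), among them Ier2 at 0.89, Jun at 0.59, Dusp1 at 0.68 and Junb at 0.91, which was 0.53 without WT 7. In these 3 lists 0 genes passed over all genes tested, and adjusted over the list alone 1 did, Ier2 (adjusted p = 0.0411). Each of the 3 calls was kept in 18 of 18 fits that left out 1 library. The NF-kB score per library was highest in KO 7, KO 8, WT 5 and KO 1, at 5.10, 5.02, 4.53 and 4.49. Without KO 7 and KO 8, which were noticed from such values, the NF-kB mean was 0.27 and its call was lost (camera adjusted p = 0.153), while without these and WT 5, of the same run of animal numbers, it was 0.45 and the call was kept (camera adjusted p = 0.00917). The call was also lost with a stricter filter on low genes (mean 0.38, adjusted p = 0.109). Among the 12 libraries of runs of animal numbers with both groups, the interferon, NF-kB and immediate early means were 0.31, 0.40 and 0.20, with camera adjusted p of 0.0120, 0.109 and 0.287. With the run as a term over these 12 they were 0.14, 0.13 and 0.10, with camera adjusted p of 0.223, 0.511 and 0.642. With KO 1 in the run of WT 6 and WT 7, the 3 means over 15 libraries with the run as a term were 0.30, 0.42 and 0.25, with camera adjusted p of 0.00113, 0.0383 and 0.0477. Without the term they were 0.36, 0.63 and 0.28 over these 15. There the immediate early call was lost (camera adjusted p = 0.0730) and the other calls were kept. Without KO 2, KO 3 and WT 7, the 3 libraries with the most genes at 0 reads, the interferon mean was 0.68 (camera adjusted p = 6.78e-18, again with the preset correlation).

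**Figure D2:**
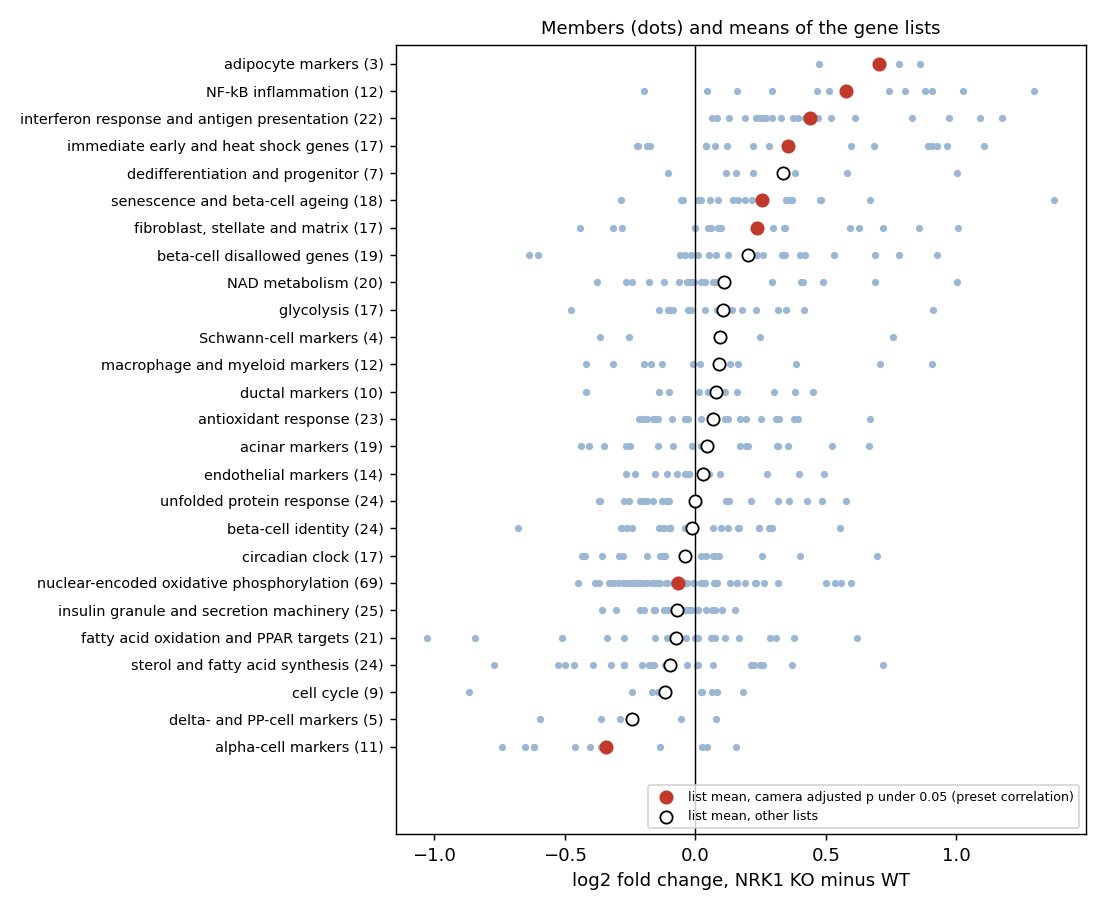
Log2 fold change, NRK1 KO minus WT, of each member (small dots) and the mean (large points) of the 26 gene lists, with the number of measured genes in brackets. Filled points mark the 8 lists with a camera adjusted p under 0.05 with the preset correlation, and 0 of them held with an estimated correlation.

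With the preset correlation, alpha-cell transcripts were called lower and adipocyte transcripts higher as groups. Estimated from these data, that correlation was 0.188 and 0.714. Of 11 alpha-cell markers, 8 were lower, with a mean of -0.34 (camera adjusted p = 0.00383, adjusted p = 0.231 with an estimated correlation). The glucagon gene Gcg was at -0.74, Ttr at -0.62 and Pou3f4 at -0.65. The 3 measured adipocyte markers were all higher, with a mean of 0.70 (camera adjusted p = 0.00113, adjusted p = 0.231 with an estimated correlation). They were the lipid carrier Fabp4 at 0.78, Car3 at 0.86 (4 to 54 reads per library) and the adipokine Adipoq at 0.47 (7 to 44 reads). Adjusted over the list alone Fabp4 and Car3 passed (adjusted p = 0.00270 and 0.0285), while over all genes 0 did. As a score per library the adipocyte markers were 3.45 ± 0.68 (SD, n = 10) in the knockout and 2.74 ± 0.36 (SD, n = 8) in WT, which did not pass over the 9 marker lists (exact permutation p = 0.0188, adjusted p = 0.169). The alpha-cell score was 4.95 ± 0.46 (SD, n = 10) against 5.29 ± 0.36 (SD, n = 8; exact permutation p = 0.104, adjusted p = 0.470). Over the 12 libraries of runs with both groups, the adipocyte mean was 0.44 (camera adjusted p = 0.117) and the alpha-cell mean -0.32 (camera adjusted p = 0.109). With the run as a term they were 0.39 (camera adjusted p = 0.220) and -0.45 (camera adjusted p = 0.0215), and with KO 1 in the run of WT 6 and WT 7 they were 0.62 and -0.43 (camera adjusted p = 0.0113 and 0.00104). Over these 15 libraries without the term, the alpha-cell call was lost at -0.25 (camera adjusted p = 0.0772) and the adipocyte call was kept. With a stricter filter on low genes the alpha-cell mean was -0.30 and its call was lost (camera adjusted p = 0.0506).

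**Figure D3:**
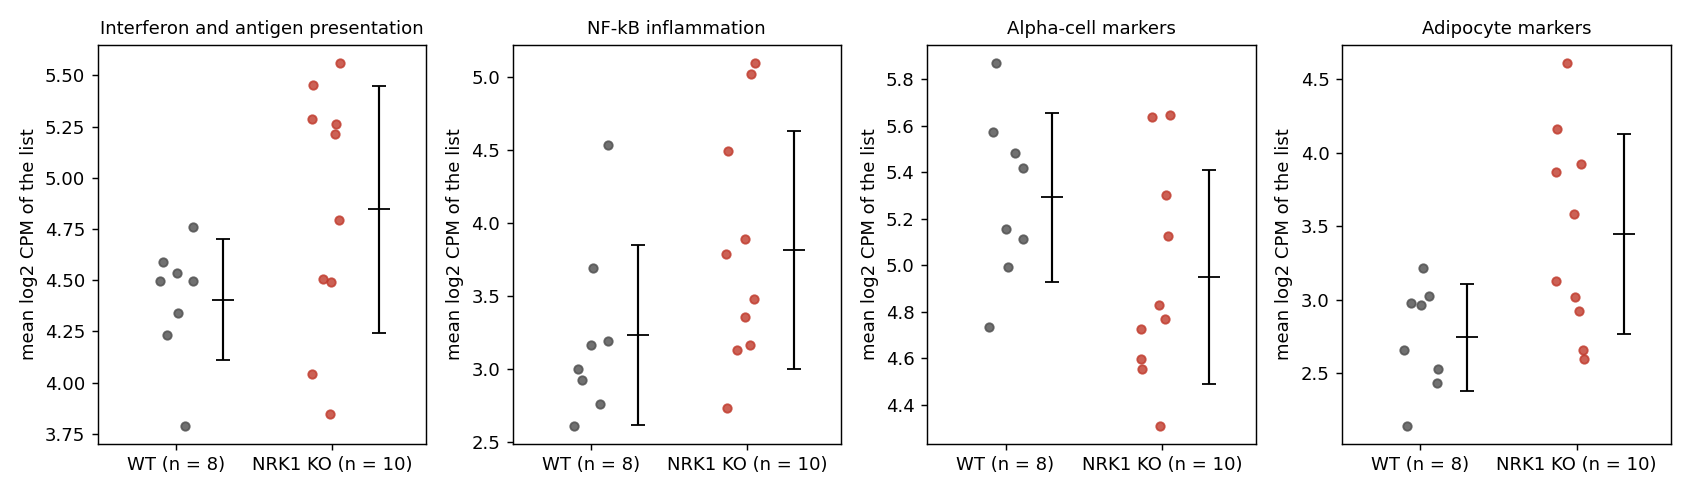
Mean log2 CPM over the members of 4 lists in each library, 1 point per mouse, for WT (n = 8) and NRK1 KO (n = 10), with the group mean and SD beside the points. The groups overlapped in all 4 lists, and the NF-kB scores of KO 7 and KO 8, 5.10 and 5.02, lay above the highest WT score of 4.53.

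With the preset correlation, senescence and matrix genes were called higher and oxidative phosphorylation genes lower as groups. Estimated from these data, that correlation was 0.044, 0.211 and 0.393. The 3 calls depended on single libraries. Of 18 senescence and beta-cell ageing genes, 15 were higher, with a mean of 0.26 (camera adjusted p = 0.0213, adjusted p = 0.231 with an estimated correlation). Its leading members were the metalloproteinase inhibitor Timp1 at 1.38 (0 to 46 reads per library), the growth factor binding proteins Igfbp5 at 0.37 and Igfbp7 at 0.35, and Tnfrsf11b at 0.67 (0 to 22 reads). The call was lost without any one of KO 1, KO 9, KO 10, WT 5 or WT 8, with adjusted p from 0.0501 to 0.0784, and over the 12 libraries of runs with both groups, without the run as a term (mean 0.06, adjusted p = 0.629) and with it (0.07, 0.651). A stricter filter on low genes also lost it (mean 0.096, camera adjusted p = 0.195). Of 17 fibroblast and matrix genes, 12 were higher, with a mean of 0.24 (camera adjusted p = 0.0343, adjusted p = 0.446 with an estimated correlation), among them Fn1 at 0.86 (2 to 30 reads per library), Fbn1 at 1.01 (0 to 34 reads), Col1a2 at 0.63 and Col4a1 at 0.34. That call was lost without any one of KO 1, KO 2, KO 3, KO 4, KO 7, KO 9, WT 2, WT 3, WT 4 or WT 5, with adjusted p from 0.0516 to 0.245. Of 69 nuclear-encoded oxidative phosphorylation genes, 47 were lower, with a mean of -0.07 (camera adjusted p = 0.0246, adjusted p = 0.752 with an estimated correlation), a mean that became 0.03 without KO 2 (adjusted p = 0.879), 0.02 with sample weights, 0.11 with stromal covariates and 0.04 without KO 2, KO 3 and WT 7. Ndufa2 was at -0.26, Ndufab1 at -0.45 and Ndufa11 at -0.33, and Uqcrfs1 was at 0.50. This call was also lost without any one of KO 3, KO 7, KO 8, WT 2, WT 3, WT 4 or WT 5, with adjusted p from 0.0543 to 0.178, with quantile normalization (adjusted p = 0.0959), with voom (0.0534), without KO 7 and KO 8 (0.168) and without these and WT 5 (0.467), while over the 12 libraries the mean was -0.28 without the run term and -0.32 with it (camera adjusted p = 8.72e-08 and 1.28e-10). The p-values over the 12 libraries also used the preset correlation. The 12 hold KO 2 and KO 3, which had the lowest scores of this list among the 18 libraries, 4.70 and 5.24. The fibroblast call was also lost with quantile normalization (adjusted p = 0.0717), sample weights (0.0983), voom (0.0534) and camera on ranks (0.0551), without KO 2, KO 3 and WT 7 (0.209) and without KO 7, KO 8 and WT 5 (0.134), and was kept over the 12 libraries without the run term (mean 0.41, camera adjusted p = 0.00628) and with it (0.46, 0.000520). In these 3 lists 0 genes passed over all genes tested and 0 adjusted over the list alone.

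Beta-cell genes showed no difference that passed as groups. Of 24 beta-cell identity genes, 10 were higher and 14 lower, with a mean log2 fold change of -0.01 (camera adjusted p = 0.631), with Slc30a8 at -0.24, Ero1b at -0.29 and the maturity marker Ucn3 at -0.28, and the mean became 0.01 with quantile normalization. Of 25 genes of the insulin granule and secretion machinery, 7 were higher and 18 lower, with a mean of -0.07 (camera adjusted p = 0.205), with Stx1a at -0.36, Scg3 at -0.16 and Vamp2 at -0.21. The 20 NAD metabolism genes had a mean of 0.11 (camera adjusted p = 0.228). Among them Nadsyn1, an enzyme that makes NAD, was at 1.00 (0 to 16 reads per library), Nampt at 0.41, the deacetylase Sirt2 at 0.41 and Nadk at 0.49, none of which passed. The 24 genes of the unfolded protein response had a mean of -0.00136 and a median of -0.11 (camera adjusted p = 0.631), with Pdia4 at -0.36, Ppp1r15a at 0.58, Xbp1 at 0.43 and Manf at 0.49, the last 2 at 0.25 and 0.26 without WT 7. Over the 12 libraries of runs with both groups this list passed, with a mean of -0.22 without the run term and -0.32 with it (camera adjusted p = 0.0151 and 1.54e-05). These 12 hold KO 2 and KO 3, which had the 2 lowest scores of this list among the 18, 5.83 and 5.71. Over all 18 libraries less KO 2, KO 3 and WT 7, without a run term, the mean was 0.11 (camera adjusted p = 0.229). That set holds libraries outside the 12, such as KO 1, KO 9 and KO 10, so it does not explain the call over the 12. Scores were 6.03 and 6.47 in KO 4 and KO 5 against 6.53 and 6.44 in WT 3 and WT 4 of the same run. They were 6.60, 6.38 and 6.65 in KO 6, KO 7 and KO 8 against 6.73 in WT 5 of their run. The 7 dedifferentiation genes had a mean of 0.34 (camera adjusted p = 0.0972), with Hes1 at 0.58, Aldh1a3 at 1.00, Vim at 0.22 and Sox9 at 0.38. Of 19 beta-cell disallowed genes, 14 were higher, with a mean of 0.20 (camera adjusted p = 0.0924). In these 6 lists 0 genes passed over all genes tested and 0 adjusted over the list alone.

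No list of markers of other cell types passed as a score per library. Of 9 marker lists, 0 passed in exact permutation tests, with 1 at an unadjusted p under 0.05. The acinar score ranged from 1.37 in KO 7 to 6.34 in KO 5 and was 3.81 ± 1.45 (SD, n = 10) in the knockout and 3.76 ± 1.53 (SD, n = 8) in WT (exact permutation p = 0.947). Its members Cpa1, Cpb1, Rnase1 and Zg16 were at 0.66, 0.53, -0.35 and -0.44. Single libraries moved these values, with Cpa1 at -0.0361 without WT 7 and Zg16 at -0.0457 without WT 4. The myeloid score differed by 0.09 (exact permutation p = 0.729), the endothelial score by 0.03 (p = 0.720, exact), the fibroblast score by 0.24 (p = 0.217, exact), the ductal score by 0.08 (p = 0.618, exact), the Schwann-cell score by 0.10 (p = 0.642, exact) and the delta- and PP-cell score by -0.24 (p = 0.476, exact). Their adjusted p lay between 0.652 and 0.947, and camera adjusted p for the 6 of these lists other than fibroblasts between 0.205 and 0.989. Over the 12 libraries of runs with both groups the delta- and PP-cell mean was -0.35 without the run term and -0.52 with it (camera adjusted p = 0.212 and 0.0249). The acinar list was called by camera with stromal covariates (mean 0.58, adjusted p = 0.00204), without KO 7 and KO 8 (0.51, 0.00409) and without these and WT 5 (0.45, 0.0142), while its mean was -0.44 over the 12 libraries (0.109). The other uncalled lists were glycolysis (mean 0.11, camera adjusted p = 0.205), fatty acid oxidation (-0.07, 0.491), sterol and fatty acid synthesis (-0.10, 0.0734), the antioxidant response (0.07, 0.957), the cell cycle (-0.12, 0.680) and the circadian clock (-0.04, 0.205). Glycolysis was called with sample weights (mean 0.24, camera adjusted p = 0.00171) and without KO 2, KO 3 and WT 7 (0.30, 7.50e-05). In fatty acid oxidation 1 gene passed adjusted over the list alone, Eci1 (adjusted p = 0.0175), and in sterol synthesis 1 did, Hmgcs1 at -0.77 (adjusted p = 0.0481), which is named here because of that count. The median differed in sign from the mean for the cell cycle (median 0.02), Schwann-cell (median -0.00444) and endothelial (median -0.0247) lists, and camera's direction was down for the first 2 and up for the last.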

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

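The tests of explanations in this part were chosen after the result was seen, except the tests of the run similarity without 3 libraries and with the acinar score removed, which were written down before their values were known. The criterion for distant values was set beforehand.

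Some values lay far from the rest of their group. In WT, Ucn3 was lowest in WT 1 at 8.12, and in WT 7 the lowest values were Sirt2 at 4.12, Ndufab1 at 3.54, Socs3 at -0.0398, Junb at 1.78 and Rnase1 at -0.83, the floor. WT 7 also had the most genes at 0 reads, 346 against at most 150 in the other WT libraries, and the largest residual SD of that group, 0.772. In the knockout, KO 3 had the lowest Xbp1 at 3.98, Nampt at 3.87, Igfbp7 at 3.87 and Ifit1 at 1.88. KO 2 had the lowest Ndufa2 at 7.34, Ndufab1 at 2.45, glycolysis score at 4.36 and circadian score at 4.03. The criterion was Dixon's, the gap to the nearest value over the range of the group. These were 16 of 192 groups of values tested, 8.33%, where chance gives about 5%, or 1 in 20, for independent and normally distributed values. The values tested overlap, since named genes also enter list scores, so the 2 percentages cannot be compared as a test. Of the 16, 15 were in KO 2, KO 3 or WT 7, the 3 libraries with the most genes at 0 reads, and the 15 include that number itself in WT 7.

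The first pattern is lower Ins1 relative to Ins2 in the knockout libraries. Ins1 and Ins2 are both beta-cell genes, so a lower share of beta cells would lower both and by itself leave their ratio unchanged. The test over identity genes therefore bears on the share and not on the ratio. The 22 other identity genes had a mean log2 fold change of 0.00620 (bootstrap interval -0.09 to 0.10), which argues against a share low enough to lower these genes as a group. The list was not restricted to genes expressed in beta cells alone, so a smaller fall of the share stays open. Different animal runs in the groups are also argued against, since the difference within runs was -1.10 (exact permutation within runs, p = 0.0208), or -1.01 with KO 1 placed in the run of WT 6 and WT 7 (p = 0.00694). The fold of 0.513 (bootstrap interval 0.392 to 0.662) is near that of losing 1 of 2 Ins1 copies, as when the Cre driver replaces a copy in the knockout mice only, so a candidate explanation is the driver allele rather than loss of NRK1. Ins1 itself had a fold of 0.625 and Ins2 a fold of 1.22, so the fold of the ratio rests in part on higher Ins2. Every title, those of WT included, holds the driver's name, which may only name the line, and the labels do not say whether WT mice carried Cre, in which case the driver would not explain the difference, so the driver and an effect of the knockout stay open as hypotheses, and so do reads shared between Ins1 and Ins2, which were not tested.

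The second pattern is the higher interferon and NF-kB list values in the knockout. Myeloid RNA cannot be told apart from a change in islet cells, because the myeloid score differed by 0.0904 with a bootstrap interval of -0.34 to 0.56, wide enough to hold the interferon difference of 0.44. Animal runs that differ between the groups cannot be told apart either: over the 12 libraries the run term changed the interferon mean from 0.31 to 0.14, a ratio of 0.46596, with score differences of -0.12, 0.26 and 0.35 within the 3 runs, while without the first, that of KO 2 and KO 3, the ratio was 0.719. The NF-kB ratios were 0.333 and 0.340, but with KO 1, whose animal number has 1 digit more than the others, in the run of WT 6 and WT 7 the ratios were 0.830 for interferon and 0.662 for NF-kB. In that run the interferon score difference was 0.955, with 1 knockout library. Chance could not be excluded: 14 of 100 splits of the samples, the real one included, called as many lists as the real 8 (highest other 13), and 11 of 100, the real one included, gave an interferon statistic as large as the real 7.58 on the -log10 p scale (highest other 10.97), and loss of NRK1 also stays open.

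The third pattern is that libraries with consecutive animal numbers resembled each other. Their residuals correlated across genes by 0.112 more than those of other pairs (permutation p = 0.00149). Libraries with many genes at 0 reads are argued against as the whole cause, since the excess stayed at 0.0911 without KO 2, KO 3 and WT 7 (permutation p = 0.00787). With the acinar score removed the excess was 0.0317 (permutation p = 0.150), so acinar RNA may account for much of it, while the fall of the excess and a shared litter, cage or day were not tested. With KO 1 in the run of WT 6 and WT 7 these 3 values were 0.107, 0.0937 and 0.0368 (permutation p = 0.00156, 0.00610 and 0.108). Acinar scores were not alike in every run. They ranged from 3.29 to 4.11 in the run of KO 2 and from 4.34 to 6.34 in that of KO 4. In the run of KO 6 they ranged from 1.37 to 5.79.

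For the count of genes called, 100 of 100 splits reach the real 0 by construction, so they say nothing about it. Of 100 splits, 37 with the real one included had as many genes at an unadjusted p under 0.05 as the real 567 (highest other 2008), so chance was not excluded for that count. Another split called 270 genes, and what set that split apart was not tested.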

How the results depend on the processing

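Leaving out libraries, runs as a term and exact permutation of list scores were settings chosen after the data were seen, except leaving out each sample in turn. The count of genes called was 0 in each of 38 alternatives (smallest adjusted p 0.0795, without KO 2, KO 3 and WT 7), so the count of 0 did not depend on a setting. The Ins1 to Ins2 ratio kept its sign and a p under 0.05 in 22 alternatives, from -1.03 to -0.79. The difference of -1.10 over the 12 libraries with the run as a term was not among these 22 and lay outside that range. No marker list passed in 24 alternatives. Of 929 values of list means, 796 kept direction and side of the threshold, 54 lost a call, 4 of them with a change of sign, 26 gained one and 53 others changed sign. Of 2312 values of named genes, 2301 kept both and 11 changed sign. Omitting the filter removed no gene and gave no separate value, quantile normalization fixes Ins1 and Ins2 at their ranks and a covariate made from a list was not tested on that list. No paired analysis was possible because the labels give no shared replicate numbers, and the run term groups mice by consecutive animal numbers without pairing them. The cause was not tested for the changes below unless stated.

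The number of called lists was 8, and 3 with the stricter filter, 4 over the 12 libraries of runs with both groups, 5 with the run term added, 10 without KO 7 and KO 8, 9 without these and WT 5, and 0 with an estimated correlation, with fry and with exact permutation of list scores, where 5, 3 and 4 lists had an unadjusted p under 0.05. It was 5 to 9 with each sample left out, 5 without WT 5. Leaving out 1 sample also gave calls absent with all samples: glycolysis at 0.21 without KO 2 (camera adjusted p = 0.004995), called too with sample weights and without KO 2, KO 3 and WT 7, dedifferentiation at 0.39 without KO 8 (0.0417), delta- and PP-cell markers at -0.35 without KO 7 and -0.39 without WT 7 (0.0456 and 0.0292), and sterol synthesis at -0.14 to -0.12 without KO 5, KO 6, KO 7, KO 8, WT 1 or WT 8 (0.0123 to 0.0426). With the stricter filter, which left 7760 genes and fewer than 3 adipocyte markers, the calls of the NF-kB, senescence, alpha-cell and fibroblast lists were lost (adjusted p = 0.109, 0.195, 0.0506 and 0.0803), and ductal and myeloid means were -0.0499 and -0.0535. Without KO 7 and KO 8, acinar, delta- and PP-cell, sterol synthesis and dedifferentiation lists were called at 0.51, -0.44, -0.16 and 0.39 (0.00409, 0.00895, 0.00869 and 0.0486), and the first 3 also without these and WT 5 at 0.45, -0.39 and -0.12 (0.0142, 0.0315 and 0.0456). Over the 12 libraries 581 genes had an unadjusted p under 0.05, and 919 with the run term, against 567 over all 18. Over the 12 without the term, Manf, Tnfrsf11b and Cpa1 were at -0.0933, -0.20 and -0.29, and the antioxidant, acinar, ductal, endothelial, myeloid and Schwann-cell means at -0.0543, -0.44, -0.11, -0.0226, -0.0321 and -0.24. With the term, Manf, Tnfrsf11b and Junb were at -0.22, -0.37 and -0.12, and the glycolysis, antioxidant, acinar, ductal and Schwann-cell means at -0.0187, -0.14, -0.16, -0.15 and -0.22.

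With KO 1 in the run of WT 6 and WT 7, 5 lists were called over the 15 libraries and 10 with the run term added, with 606 and 652 genes at an unadjusted p under 0.05. Without the term, the immediate early, alpha-cell and senescence calls were lost at 0.28, -0.25 and 0.14 (camera adjusted p = 0.0730, 0.0772 and 0.370), Nmrk1 was at 0.00994, and the beta-cell identity, glycolysis, endothelial and Schwann-cell means at 0.00117, -0.00733, -0.0119 and -0.11. With the term, the senescence call was lost at 0.15 (0.229), unfolded protein, delta- and PP-cell and sterol synthesis lists were called at -0.20, -0.42 and -0.16 (0.000227, 0.0142 and 0.0113), Nmrk1 was at 0.00783, and the beta-cell identity, antioxidant, ductal and Schwann-cell means at 0.00902, -0.0335, -0.0224 and -0.10.

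Nmrk1, near 0, was at 0.000265 with sample weights, 0.19 with stromal covariates, 0.0582 without KO 7 and KO 8, and from -0.24 to 0.16 with each sample left out. With sample weights the unfolded protein and oxidative phosphorylation means were 0.0445 and 0.0236. With stromal covariates Vim was at -0.0241, Zg16 at 0.18, and the beta-cell identity, unfolded protein, oxidative phosphorylation and circadian means at 0.00187, 0.13, 0.11 and 0.00933. The unfolded protein mean was 0.0151 with voom, 0.11 without KO 2, KO 3 and WT 7, and 0.0110 without KO 7, KO 8 and WT 5. Without KO 2, KO 3 and WT 7 the oxidative phosphorylation, cell cycle and acinar means were 0.0421, 0.0115 and -0.19. Without KO 7 and KO 8, Zg16 was at 0.0487 and the beta-cell identity and fatty acid oxidation means at 0.00362 and 0.0201. The identity mean was 0.00544 with quantile normalization, and Slc30a8 was at 0.0102 by medians in the rank-sum test. By medians over markers the delta- and PP-cell, ductal and Schwann-cell scores differed by 0.0804, -0.22 and -0.0518.

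With each sample left out, means ranged from -0.0315 to 0.0155 for beta-cell identity, -0.0570 to 0.0682 for the unfolded protein response, -0.13 to 0.0342 for oxidative phosphorylation, -0.11 to 0.00416 for the circadian clock, -0.27 (without WT 7) to 0.39 (without WT 4) for acinar markers, -0.00579 to 0.0637 for endothelial and -0.0399 to 0.19 for myeloid markers, and from -0.0361 to 1.12 for Cpa1. List means that kept their sign and moved by over 1.5 times ranged from 0.0306 to 0.14 for the antioxidant response, -0.18 to -0.0339 for the cell cycle, -0.39 to -0.10 for delta- and PP-cell, 0.0135 to 0.17 for ductal and 0.0106 to 0.19 for Schwann-cell markers, -0.11 to -0.0163 for fatty acid oxidation, 0.0545 to 0.21 for glycolysis, 0.0709 to 0.14 for NAD metabolism and -0.14 to -0.0581 for sterol synthesis. Other named genes moved by over 1.5 times: Stx1a to -0.20, Ucn3 to -0.18, Vim to 0.07, Col4a1 to 0.21, Ndufa11 to -0.20 and Ndufab1 to -0.27 without KO 2, Aldh1a3 to 0.65 without WT 8, and Igfbp7 to 0.20 without WT 7 and 0.54 without KO 3. Vamp2 moved so to -0.12 without KO 2 and -0.14 without WT 5 or WT 7, and Sox9 to 0.23 without KO 1 or KO 6, 0.25 without KO 7 and 0.68 without KO 4. The acinar genes Cpb1, Rnase1 and Zg16 ranged from 0.20 to 0.91, -0.80 to -0.16 and -0.78 to -0.0457. Depth limited genes with few reads, such as Nmrk1 with 3 to 36 per library.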

Other observations

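The leading components of the islet libraries did not pass a test between genotypes. The first 4 principal components held 17.3%, 13.1%, 8.69% and 6.69% of the variance (exact permutation p = 0.889, 0.181, 0.785 and 0.375). Among transcripts of other endocrine cells, Gcg had 5996 to 42569 reads per library, Sst 2207 to 11992 and Ppy 446 to 5790. The acute phase and complement genes Lcn2 and Cfb, looked at after the data were seen, had 0 to 244 and 0 to 341 reads, with 244, 160 and 128 reads of Lcn2 in KO 7, KO 8 and WT 5, whose animal numbers are consecutive. KO 6, of the same run, had 1, and the next highest were KO 5 with 81 and KO 1 with 53.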
